A study of Homo sapiens with 6 samples.

How the data were processed

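RNA was measured in HCT116, an established human colorectal carcinoma cell line that the sample titles give as HCT116 +/+, on Affymetrix Human Exon 1.0 ST arrays, which carry several probe sets per gene. Of the 6 arrays, 2 were controls, 2 had received Nutlin-3 and 2 had received 5-fluorouracil (5FU), and cells were collected after 12 h, per the series' design text. The labels give the control treatment as none while the design text names DMSO, and the labels name the PicoPure kit for RNA while the design text names RNeasy. The labels say Nutlin 3R where the design text says Nutlin-3, so whether 1 enantiomer or the mixture was used is not known here, and doses are not given in the sources used here. None of these points could be settled. Groups and replicate numbers came from the sample labels. The labels do not say that replicates were separate cultures, so every p-value measures only the spread between these samples, which may be technical.

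The deposited values are log2 expression values per probe set, and RMA is named in the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises probes on a log2 scale. Its version and settings are not given in the sources used here. The background correction could not be varied from these values, and array slides, scan days and other batches are not given in the sources used here. The table held 1411399 probe sets with 0 missing values. Array medians lay between 4.73 and 4.78. RMA values carry no count or detection call, so the number of arrays limits the precision.

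Probe sets were named through the platform annotation supplied with the table. It gave 1 gene symbol to 357604 probe sets, several to 15322 and none to 1038473; probe sets with several symbols named no gene. Of 19560 symbols, 16472 were current in the RefSeq gene table of assembly GRCh38.p14, 2966 were updated through a unique synonym and 122 were kept as annotated. That table was used for names and for neighbouring genes, and no coordinates are given because no genome build was named.

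A gene's value on an array was the mean log2 value of its probe sets whose mean over the 6 arrays exceeded the median of all probe-set means (4.73), with at least 2 such probe sets, which left 17841 genes with a median of 12 probe sets. Histones and other near-identical gene copies, and overlapping genes such as FAS and ACTA2, may share signal and are uncertain to that extent. The 3 groups were fitted in 1 linear model with limma (lmFit and eBayes, no block, 3 residual degrees of freedom), and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. The same model was fitted to 705699 probe sets above the median. With 2 arrays against 2, an exact two-sided permutation test of 1 gene cannot go below 0.333, so calls rest on the variance that limma shares across genes.

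Lists of genes were tested with camera in limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 21 lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were run beside it. The lists were p53 targets in 4 groups (cell-cycle arrest and growth, apoptosis, negative feedback on p53, DNA repair and metabolism), mitosis and G2/M genes, DNA replication and G1/S genes, replication-dependent histones, pyrimidine, folate and fluoropyrimidine metabolism, DNA damage signalling and homologous recombination, ribosome biogenesis and nucleolus, the RNA exosome, cytosolic ribosomal proteins, NF-kappaB and inflammatory genes, interferon-stimulated genes, the unfolded protein and integrated stress response, cholesterol and fatty-acid synthesis, immediate early and AP-1 genes, autophagy and lysosome genes, and colonic epithelial, fibroblast and blood cell markers. Some genes belong to several lists, among them TP53INP1, SESN1, SESN2 and RRM2, so results of different lists are not independent. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. That rule took, per comparison, the 10 largest rises and 10 largest falls among called genes with at least 3 used probe sets and groups that did not overlap, up to 4 called members of each list with the largest change, and, whatever their values, MDM2, CDKN1A, TYMS, ATM and MET; a further item of the rule is not reported here.

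The tests were tried on simulated data for the 17841 genes, in 50 sets under each of 3 kinds of noise. Independent noise and an axis fixed on the arrays were added after false calls were seen with an axis placed at random. With independent noise, 50.4% of 2-fold and 88.6% of 4-fold changes of Nutlin-3 against control were found, and 4.15% of calls were false. When the replicate differences followed the shared axis measured in these arrays, 20.6% and 76.5% were found and 0.137% of calls were false. When such an axis fell on the arrays at random, 8 of the 50 sets for Nutlin-3 against control, 8 for 5FU against control and 12 for Nutlin-3 against 5FU had over 10% false calls. An axis that happens to follow the groups can be read as an effect, but whether it did so in these sets was not checked. Over all 50 sets, 4.18%, 66% and 41.8% of calls were then false, in the same order. For lists, 50 further sets of each kind were drawn, in which only the mitosis and G2/M list was shifted, 2-fold down in Nutlin-3. For Nutlin-3 against control, camera at the preset correlation found this list in 50 of 50 sets under each kind of noise. It called 0.2%, 6.2% and 31.2% of unshifted lists. With an estimated correlation the shifted list was found in 49, 0 and 1 of the 50 sets, and fry found it in 50, 0 and 9. For this list, whose estimated correlation in the measured values was 0.699, a lost call therefore does not show that it did not move. Less correlated lists, such as p53 targets in apoptosis (0.184) or NF-kappaB genes (-0.035), were not shifted. Lost calls of such lists are not covered by these simulations.

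Alternatives changed the filter on dim probe sets or genes, the summary over probe sets, the minimum number of probe sets, the normalization between arrays, the replicate number as a block, the groups in the fit, the variance model, array weights and each array in turn. Added after the data were seen were a crossed pairing of the replicates, a covariate for the contrast of each array (the 90th percentile minus the median of its probe sets) and a fit without control replicate 2 and Nutlin-3 replicate 1. Reference values for correlation, covariance and sign agreement under shared controls came from 100 simulations of unchanged groups. Their noise was drawn independently for each array and left out the axis of replicate differences, so they hold for independent noise only. R 4.3.3, limma 3.58.1, data.table version 1.17.8, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.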

Results

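Gene expression was measured in HCT116 colorectal carcinoma cells on 6 exon arrays. Nutlin-3 is a small molecule that blocks the binding of MDM2 to p53, and 5FU is a pyrimidine analogue used in chemotherapy whose metabolites inhibit thymidylate synthase. Each drug was compared with 2 control arrays after 12 h, with 2 arrays per drug. The series concerns genes synthetic lethal with Nutlin-3, and the comparisons ask which transcripts each drug changed and where the drugs differed. All levels are deposited log2 values averaged over a gene's probe sets, given as mean ± SD with n = 2. Correlations between arrays across genes lay between 0.92 and 0.981, and the median residual SD of a gene was 0.161.

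After Nutlin-3, genes activated by p53 were higher and genes of the cell cycle were lower. TP53I3, a p53-inducible oxidoreductase, rose from 7.23 ± 0.00 in control to 10.02 ± 0.04, a 6.94-fold change (limma, Benjamini-Hochberg adjusted p = 0.000845). GDF15, a secreted cytokine of the TGF-beta family, rose 5.01-fold (adjusted p = 0.0023), and CDKN1A, the cyclin-dependent kinase inhibitor p21, rose 4.27-fold from 8.29 ± 0.03 to 10.39 ± 0.00 (adjusted p = 0.00308). MDM2, the ubiquitin ligase that restrains p53, rose 3.63-fold from 8.61 ± 0.05 to 10.46 ± 0.29 (adjusted p = 0.0099). The other largest rises were in TP53INP1 (5.1-fold), SERPINB5, which encodes maspin (4.89-fold), ABCA12, a lipid transporter (4.24-fold), DNAI3 (4.01-fold), SULF2, a heparan sulfate endosulfatase (3.69-fold), and ANKRA2 (3.43-fold). The control means of ABCA12 (4.60) and DNAI3 (4.38) lay below the probe-set filter of 4.73, so the size of their rise is less certain. CCNE2, which encodes cyclin E2, fell 7.98-fold from 7.53 ± 0.35 to 4.53 ± 0.33 (adjusted p = 0.00861), to a level below the probe-set filter, where the size of a fall is less certain, as for FAM111B (4.55 ± 0.35). MCM10, a replication initiation factor, fell 5.68-fold, and DTL, EXO1, NDC80, WDR76, CLSPN, FAM111B, CDC6 and ATAD2 fell between 5.53-fold and 4.66-fold. The Nutlin-3 means of NDC80 (5.39), WDR76 (5.36) and CLSPN (5.46) lay not far above the filter, so the size of their falls is also less certain.

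In all, limma called 217 of 17841 genes for Nutlin-3 against control, 64 higher and 153 lower, and 179 of them changed at least 2-fold. At an unadjusted p below 0.05 there were 1821. Without control replicate 1 the count was 5, without control replicate 2 it was 115, without Nutlin-3 replicate 1 it was 31 and without Nutlin-3 replicate 2 it was 131. With the replicate number as a block it was 2, and with a crossed pairing chosen after the data were seen 1788. Groups did not overlap for 34.2% of genes, where exchangeable arrays give 33.3%. Replicates of each group lay on opposite sides of a shared axis, so the share without any drug effect may be lower than 33.3%. At the level of single probe sets limma called 0 of 705699, with 43352 at an unadjusted p below 0.05. With trend and robust variances it called 2696, and with upper-quartile probe sets alone 1531.

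The 4 lists of p53 targets were higher after Nutlin-3 in camera. Of 25 measured targets in cell-cycle arrest and growth, 7 rose, among them GDF15, CDKN1A, SESN1 (2.95-fold) and the antiproliferative gene BTG2 (2.95-fold), and the list's median log2 change was 0.67 (adjusted p = 2.6e-21). Of 27 apoptosis targets, 6 rose, including the death receptors FAS (2.89-fold) and TNFRSF10B (1.91-fold), with a median of 0.49 (adjusted p = 2.6e-16). Of 12 genes in negative feedback on p53, 3 rose, MDM2, TP53INP1 and ZMAT3 (2.6-fold), with a median of 0.37 (adjusted p = 6.63e-06). Of 41 targets in DNA repair and metabolism, 9 rose, among them ANKRA2, CYFIP2 (3.09-fold), GADD45A (2.29-fold) and APOBEC3C (2.26-fold), with a median of 0.71 (adjusted p = 2.31e-32). Adjusted over the list alone, 17, 16, 6 and 30 members rose. The adjusted p with an estimated correlation was 0.151 for each list except negative feedback, where it was 0.333. Fry called these lists except negative feedback (adjusted p = 0.143).

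Mitosis and G2/M genes fell after Nutlin-3 as a list, with a median log2 change of -1.41 (camera adjusted p = 2.02e-58). Of 49 measured members, 28 fell and all 49 had values below control, among them NDC80 of the kinetochore (5.39-fold), the checkpoint kinase BUB1B (4.17-fold) and the kinesins KIF11 (4.07-fold) and KIF2C (3.76-fold). DNA replication and G1/S genes had a median of -1.26 (adjusted p = 3.96e-59), and 29 of 52 fell, among them CCNE2, MCM10, the licensing factor CDC6 (4.77-fold) and ATAD2. Replication-dependent histones had a median of -1.55 (adjusted p = 1.31e-24), and 11 of 16 fell, including H2BC14 (10.4-fold, on 2 probe sets), H2BC15, H2AC12 and the linker histone H1-4 (3.33-fold); these copies are similar in sequence and may share signal. In DNA damage signalling and homologous recombination the median was -0.94 (adjusted p = 3.15e-30), and 15 of 51 fell, including the exonuclease EXO1 (5.48-fold), the checkpoint adaptor CLSPN (5.12-fold), the helicase BRIP1 (3.82-fold) and RAD51AP1 (3.55-fold). Adjusted over the list alone, 49, 49, 14 and 33 members fell. The estimated inter-gene correlations were 0.699, 0.627, 0.499 and 0.739 in the order given, far above the preset 0.01. Camera p-values at the preset may therefore overstate the evidence. With an estimated correlation the adjusted p was 0.151 for the mitosis, replication and histone lists and 0.313 for DNA damage signalling. Fry called the first 3 and not DNA damage signalling (adjusted p = 0.0902).

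Smaller shifts after Nutlin-3 passed camera in 6 further lists. Ribosome biogenesis and nucleolus genes had a median of -0.21 (adjusted p = 1.39e-07) and RNA exosome genes a median of -0.34 (adjusted p = 7.25e-05), with 0 of 55 and 0 of 20 members called. The uracil glycosylase UNG fell 2.39-fold in the pyrimidine and folate list, where 1 of 42 was called and the median was -0.19 (adjusted p = 0.000643). In cholesterol and fatty-acid synthesis INSIG1 fell 2.44-fold and HSD17B7 rose 2.05-fold, and the median of 31 genes was -0.20 (adjusted p = 0.000813). SESN1 and TP53INP1, both also in the p53 target lists, rose in the autophagy and lysosome list, whose median was 0.08 (adjusted p = 0.00343). In the unfolded protein and integrated stress response DDIT4, an inhibitor of mTORC1, rose 3.08-fold, while the median was -0.01, the mean 0.13 and the camera direction up (adjusted p = 0.026). With an estimated correlation the adjusted p of these 6 lists was 0.51, 0.474, 0.467, 0.52, 0.528 and 0.567 in the order given, and fry called none of them (adjusted p = 0.323, 0.323, 0.293, 0.323, 0.331 and 0.402). Adjusted over the list alone, 0, 2, 2, 6, 3 and 2 members were called. The pyrimidine list lost its call without control replicate 1 (median -0.08), and the cholesterol list without control replicate 1 (-0.13) or Nutlin-3 replicate 1 (-0.12). The autophagy list lost its call without control replicate 2 (-0.02) or Nutlin-3 replicate 2 (0.005), and the stress response list without control replicate 2 (-0.02), without Nutlin-3 replicate 2 (-0.04) or with all probe sets of a gene (-0.02).

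The remaining 7 lists did not pass camera for Nutlin-3 against control. Cytosolic ribosomal proteins had a median of 0.01 with a mean of -0.001 (adjusted p = 0.64). NF-kappaB and inflammatory genes had a median of 0.02 (adjusted p = 0.0876), and fry called this list higher (adjusted p = 0.0143). Among interferon-stimulated genes the double-stranded RNA sensor TLR3 (3.1-fold) and the peptide transporter TAP1 (2.33-fold) rose, with a list median of 0.04 (adjusted p = 0.0873). Immediate early and AP-1 genes had a median of -0.06 (adjusted p = 0.081). Colonic epithelial genes had a median of 0.05 (adjusted p = 0.0611). Blood cell markers had a median of 0.11 (adjusted p = 0.0876) and fibroblast markers a median of 0.04 (adjusted p = 0.125), with ACTA2, smooth muscle actin, the 1 member of 15 that rose (3.21-fold). Adjusted over the list alone, 2 interferon-stimulated genes, 1 colonic gene and 1 fibroblast marker were called, and 0 in the other 4 lists. Ribosomal proteins passed camera without control replicate 1 (median 0.11) or Nutlin-3 replicate 1 (0.11). Immediate early genes (-0.10) and fibroblast markers (0.155) passed without control replicate 2. Colonic genes passed without control replicate 2 (0.14) or Nutlin-3 replicate 2 (0.11), as did blood cell markers (0.19 and 0.18). With the 8920 genes of higher mean alone, interferon-stimulated (0.148), colonic (0.154) and fibroblast (0.146) genes passed. With upper-quartile probe sets alone, interferon-stimulated (0.057), colonic (0.105), fibroblast (0.147) and blood cell (0.13) genes passed. Interferon-stimulated genes also passed with at least 4 probe sets a gene (0.049), and colonic genes with all probe sets of a gene (0.081). TYMS, thymidylate synthase, had a log2 difference of -0.27 (95% interval -0.65 to 0.10, adjusted p = 0.693). ATM, a DNA damage kinase, differed by -0.02 (-0.60 to 0.56, adjusted p = 0.993) and MET, a receptor tyrosine kinase, by -0.07 (-0.62 to 0.49, adjusted p = 0.976). ATM and MET are known as genes synthetic lethal with Nutlin-3, and neither passed limma's threshold in any of the 3 comparisons.

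**Figure D1:**
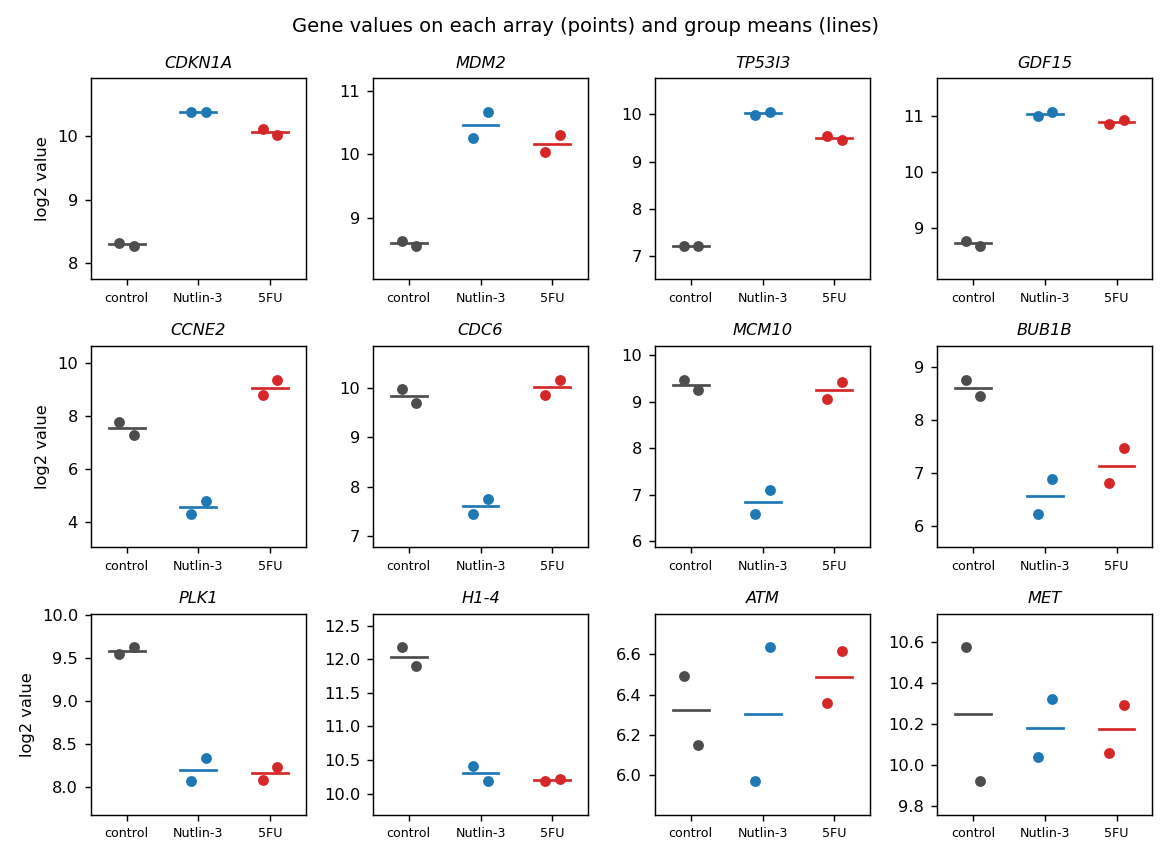
Log2 values of 12 genes on each of the 6 arrays, by group, with points for arrays and lines for group means. Each panel has its own vertical axis, which does not start at 0. CDKN1A, MDM2, TP53I3 and GDF15 lie higher after both drugs, CCNE2, CDC6 and MCM10 lie lower after Nutlin-3, and the ATM and MET values overlap between groups.

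After 5FU, p53 targets were higher and histones were lower than in control. SERPINB5 rose 5.81-fold from 6.25 ± 0.15 to 8.79 ± 0.34 (limma, Benjamini-Hochberg adjusted p = 0.026), TP53I3 rose 4.82-fold (adjusted p = 0.00356), GDF15 rose 4.53-fold (adjusted p = 0.00357) and CDKN1A rose 3.43-fold (adjusted p = 0.00751). TLR3 (4.46-fold), FAS (4.43-fold), TP53INP1 (3.83-fold), DNAI3 (3.8-fold), the glycosyltransferase GALNT5 (3.42-fold) and the aldo-keto reductase AKR1B10 (3.39-fold) completed the 10 largest rises among genes with at least 3 probe sets. The control mean of DNAI3, 4.38, lay below the probe-set filter. Those of AKR1B10 (4.74) and TLR3 (5.28) lay not far above it, so the size of these rises is less certain. Among genes with at least 3 probe sets the largest falls were in DHX32, an RNA helicase family member (4.1-fold, from 7.98 ± 0.16 to 5.95 ± 0.38, adjusted p = 0.0295), the histones H2AC21 (4.05-fold), H1-4 (3.56-fold), H2AC6 (3.23-fold), H1-2 (3.06-fold), H2AC25 (2.74-fold), H2BC15 (2.68-fold) and H2AC20 (2.61-fold), the phosphodiesterase PDE9A (2.72-fold) and the mitotic kinase PLK1 (2.67-fold).

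For 5FU against control limma called 80 of 17841 genes, 59 higher and 21 lower, with 72 at 2-fold or more and 1915 at an unadjusted p below 0.05. The count was 3 without control replicate 1, 4 without control replicate 2 and 1 without 5FU replicate 1 or 5FU replicate 2. With the replicate number as a block it was 1, with the crossed pairing 1882, and with arrays centred on their medians 14. Groups did not overlap for 38% of genes, where exchangeable arrays give 33.3%. No single probe set was called by limma (0 of 705699), with 44222 at an unadjusted p below 0.05. Trend and robust variances gave 829, and upper-quartile probe sets alone 167.

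The p53 target lists were higher after 5FU in camera, with medians of 0.89 for cell-cycle arrest and growth (adjusted p = 1.39e-23), 0.66 for apoptosis (adjusted p = 3.98e-21), 0.47 for negative feedback (adjusted p = 5.37e-06) and 0.54 for DNA repair and metabolism (adjusted p = 1.21e-23). The members that rose numbered 10 of 25, 6 of 27, 3 of 12 and 7 of 41, or 19, 19, 4 and 25 adjusted over the list alone. They included SFN, the 14-3-3 sigma protein (3.34-fold), APAF1 of the apoptosome (3.24-fold), BTG2 (3.03-fold), MDM2 (2.96-fold), SUSD6 (2.95-fold), ABHD4 (2.74-fold), BLOC1S2 (2.72-fold), CYFIP2 (2.7-fold) and the phosphatase PPM1D (2.49-fold). The adjusted p with an estimated correlation was 0.0811, 0.0918, 0.405 and 0.0918, and fry called these lists except negative feedback (adjusted p = 0.187).

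Replication-dependent histones fell as a list after 5FU, with a median of -1.22 (camera adjusted p = 5.48e-23), and 7 of 16 fell, or 13 adjusted over the list alone, led by H2BC14 (11.8-fold, on 2 probe sets). Mitosis and G2/M genes had a median of -0.50 (adjusted p = 2.31e-23), with PLK1 and the anaphase activator CDC20 (1.98-fold) the 2 of 49 that fell, or 20 adjusted over the list alone. The adjusted p with an estimated correlation was 0.12 for histones and 0.378 for mitosis, and fry called histones and not mitosis (adjusted p = 0.196). DNA replication and G1/S genes did not pass, with a median of 0.02 and a camera direction of down (adjusted p = 0.826), 0 of 52 members called and 1 called higher adjusted over the list alone. DNA damage signalling and homologous recombination had a median of 0.06 and 0 of 51 called (adjusted p = 0.966). Without control replicate 2 the replication list passed with a median of -0.14, and the DNA damage list passed in opposite directions without control replicate 1 (0.22) and without control replicate 2 (-0.14). Pyrimidine, folate and fluoropyrimidine metabolism had a median of 0.07 and 0 of 42 called (adjusted p = 0.328), and TYMS differed by 0.07 on the log2 scale (95% interval -0.31 to 0.44, adjusted p = 0.966). ATM differed by 0.17 (-0.41 to 0.74, adjusted p = 0.929) and MET by -0.07 (-0.63 to 0.48, adjusted p = 0.975).

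NF-kappaB and inflammatory genes were higher after 5FU, with a median of 0.40 (camera adjusted p = 1.33e-08). The apoptosis inhibitor BIRC3 (3.14-fold) and the chemokine CXCL8 (1.99-fold) were the 2 of 26 that rose, or 11 adjusted over the list alone. Interferon-stimulated genes had a median of 0.24 (adjusted p = 5.37e-06), with TLR3 and TAP1 (2.33-fold) the 2 of 40 called, and the same number adjusted over the list alone. Both lists had an adjusted p of 0.0811 with an estimated correlation, and fry called both. Immediate early and AP-1 genes had a median of 0.15 (adjusted p = 0.00338, and an adjusted p of 0.488 with an estimated correlation), with 0 of 28 called and 5 adjusted over the list alone. This call was lost without control replicate 2 and Nutlin-3 replicate 1 together, a fit chosen after the data were seen (median 0.07, adjusted p = 0.0898). SESN2, a stress-induced sestrin (2.06-fold), and TP53INP1, both also in the p53 target lists, rose in the autophagy and lysosome list. The median of this list was 0.12 (adjusted p = 0.00251, and an adjusted p of 0.815 with an estimated correlation). In it, 4 genes were called adjusted over the list alone, and the list lost its call without control replicate 2 (0.02). HSD17B7 rose 2.51-fold while the cholesterol and fatty-acid list had a median of -0.04 (adjusted p = 0.0343), and ribosome biogenesis and nucleolus genes had a median of -0.07 (adjusted p = 0.0235); both had an adjusted p of 0.892 with an estimated correlation. Without control replicate 1 the ribosome biogenesis median was 0.09 and the cholesterol median 0.02, and without 5FU replicate 1 they were 0.06 and 0.002, none of which passed. With the median over probe sets they were -0.05 (adjusted p = 0.196) and -0.17 (adjusted p = 0.0618), so both calls were lost although the cholesterol median was further from 0. Fry did not call the immediate early (adjusted p = 0.187), autophagy (0.433), cholesterol (0.8) or ribosome biogenesis (0.807) lists after 5FU. Adjusted over the list alone, 1 cholesterol gene and 0 ribosome biogenesis genes were called.

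Lists that did not pass camera for 5FU against control were the RNA exosome (median -0.05, adjusted p = 0.123), cytosolic ribosomal proteins (0.10, adjusted p = 0.152), the unfolded protein and integrated stress response (-0.02, adjusted p = 0.846), colonic epithelial genes (0.08, adjusted p = 0.144) and blood cell markers (-0.06, adjusted p = 0.254). Fibroblast markers had a median of -0.03 with a mean of 0.08 and a camera direction of up (adjusted p = 0.813), and ACTA2 rose 2.51-fold. SESN2, also in the p53 target and autophagy lists, was the 1 stress response gene that rose. Adjusted over the list alone, 2 stress response genes were higher and 4 lower, and 2 colonic genes were higher. Exosome genes passed without control replicate 2 (-0.18) or 5FU replicate 2 (-0.19), ribosomal proteins (0.16) and blood cell markers (-0.19) without control replicate 1, and colonic genes without control replicate 2 (0.11). Ribosomal proteins also passed with the median over probe sets (0.129), and colonic genes with the 8920 genes of higher mean (0.13).

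**Figure D2:**
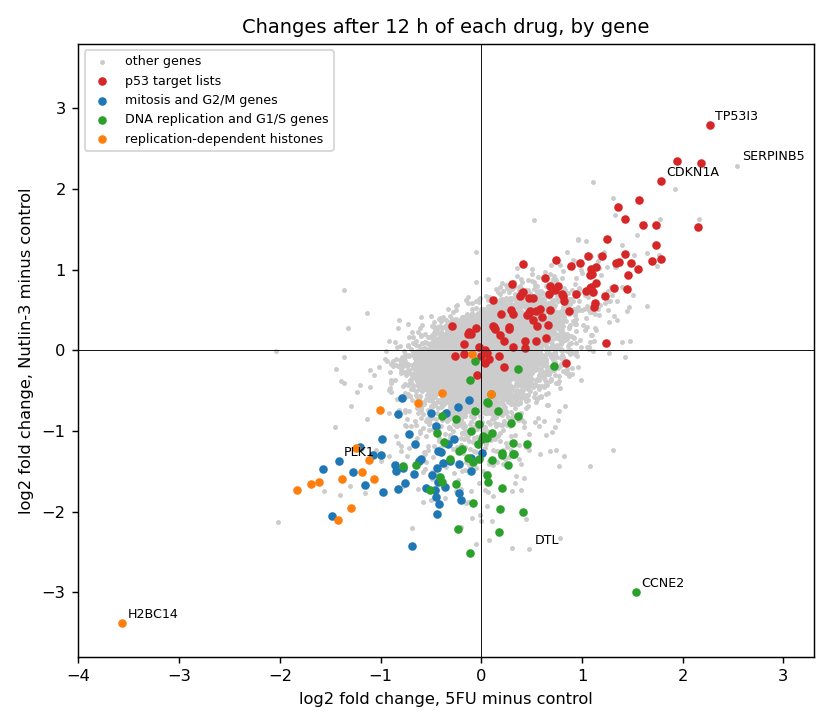
Log2 fold change against control for each of 17841 genes, with 5FU on the horizontal axis and Nutlin-3 on the vertical axis, and members of 4 kinds of list in colour. p53 targets spread towards the upper right and histones towards the lower left, while DNA replication genes lie below 0 for Nutlin-3 with a median of 0.02 for 5FU.

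Both drugs were called in the same direction for 41 genes, 31 higher and 10 lower, and 0 genes were called in opposite directions. CDKN1A, MDM2, TP53I3, GDF15, FAS and SERPINB5 were among those higher, and PLK1, CDC20 and 8 histone genes made up those lower. Independent lists of these sizes would share 0.21 higher and 0.18 lower. The correlation of log2 fold changes across genes was 0.4, where simulated unchanged groups with shared controls and independent noise gave 0.5, and genes are not independent replicates. The sign was the same for 59.3% of genes, against 66.6% in simulation, and the covariance was 0.0349 against 0.0174. The simulated noise was independent for each array and left out the axis that replicates shared. These references therefore do not show whether the drugs agree more or less than shared controls alone give. The controls could not be split into parts of 2 arrays, so part of the overlap may come from the shared controls. The shared count was 3 without control replicate 1, 4 without control replicate 2, 15 without Nutlin-3 replicate 1, 22 without Nutlin-3 replicate 2 and 1 without 5FU replicate 1 or 5FU replicate 2. With the replicate number as a block it was 1.

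Set directly against each other, the drugs differed most in replication genes, which were lower after Nutlin-3 than after 5FU. CCNE2 lay at 4.53 ± 0.33 after Nutlin-3 and 9.06 ± 0.42 after 5FU, a 23.1-fold difference (limma, Benjamini-Hochberg adjusted p = 0.00502). FAM111B was 8.64-fold lower (adjusted p = 0.00502), and the Nutlin-3 means of CCNE2 and FAM111B (4.55) lay below the probe-set filter, so both folds are uncertain in size. DTL, a substrate adaptor of the CUL4 ubiquitin ligase, was 7.68-fold lower (adjusted p = 0.00604), EXO1 6.79-fold, and the transcription factors MYBL1 and E2F8 5.83-fold and 5.81-fold. TCF19, CDC6, CLSPN and the phosphatase CDC25A were between 5.69-fold and 5.37-fold lower. In the other direction DHX32 was 4.08-fold higher after Nutlin-3 than after 5FU, the neurotensin receptor NTSR1 3.02-fold, CMTM4 2.44-fold, the nuclear long non-coding RNA NEAT1 2.4-fold, PDE9A 2.31-fold, DDIT4 2.15-fold, PLPP6 2.01-fold, the kinase NEK6 1.95-fold, the zinc transporter family member SLC39A11 1.9-fold and PLEKHH1 1.87-fold.

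Limma called 113 of 17841 genes for Nutlin-3 against 5FU, 11 higher and 102 lower, with 100 at 2-fold or more and 2377 at an unadjusted p below 0.05. The count was 9 without Nutlin-3 replicate 1, 51 without Nutlin-3 replicate 2, 18 without 5FU replicate 1 and 3 without 5FU replicate 2. With the replicate number as a block it was 0, with 1821 at an unadjusted p below 0.05. With the crossed pairing, which keeps Nutlin-3 and 5FU replicates of 1 number together and swaps the controls, it was 2821. Groups did not overlap for 46% of genes, where exchangeable arrays give 33.3%. At the level of probe sets 10 of 705699 were called, all lower after Nutlin-3, in CCNE2, FAM111B, DTL, TCF19 and ZNF367, the last a zinc-finger gene chosen after its values were seen. Without 5FU replicate 1 the count was 1, and without control replicate 1, control replicate 2, Nutlin-3 replicate 1, Nutlin-3 replicate 2 or 5FU replicate 2 it was 0.

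DNA replication and G1/S genes had a median log2 difference of -1.17 between Nutlin-3 and 5FU (camera adjusted p = 9.47e-48), with 26 of 52 lower and 50 lower adjusted over the list alone, among them CCNE2, CDC6, CDC25A and MCM10 (5.26-fold). DNA damage signalling and homologous recombination had a median of -0.92 (adjusted p = 3.92e-24), with 11 of 51 lower and 35 adjusted over the list alone, among them EXO1, CLSPN, the recombination gene XRCC2 (4.12-fold) and BRIP1 (3.99-fold). Mitosis and G2/M genes had a median of -0.81 (adjusted p = 1.38e-19), with 4 of 49 lower and 30 adjusted over the list alone; these were CCNA2 (3.16-fold), KIF2C (2.82-fold), the transcription factor FOXM1 (2.43-fold) and KIF23 (2.43-fold). The pyrimidine and folate list had a median of -0.28 (adjusted p = 0.000344). In it UNG (2.31-fold) and the ribonucleotide reductase subunit RRM2 (2.28-fold), which is also in the replication list, were lower, and 6 of 42 adjusted over the list alone. With an estimated correlation the adjusted p was 0.355, 0.527, 0.527 and 0.645 in that order. Fry called the replication list and not the DNA damage (adjusted p = 0.141), mitosis (0.179) or pyrimidine (0.24) lists.

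Inflammatory and immediate early genes were lower after Nutlin-3 than after 5FU. The NF-kappaB list had a median of -0.18 (camera adjusted p = 0.000214), with TNFAIP3, a deubiquitinase (2.02-fold), and CXCL8 (1.94-fold) the 2 of 26 lower, and 8 adjusted over the list alone. Immediate early and AP-1 genes had a median of -0.26 (adjusted p = 7.21e-05), with JUN (2.38-fold) and CCN1 (2.23-fold) the 2 of 28 lower, and 5 adjusted over the list alone. Interferon-stimulated genes had a median of -0.18 and 0 of 40 called (adjusted p = 0.0102). With an estimated correlation the adjusted p was 0.355, 0.527 and 0.355. The unfolded protein and integrated stress response had a median of 0.04 with DDIT4 the 1 of 41 called (adjusted p = 0.0299, and an adjusted p of 0.842 with an estimated correlation). Ribosome biogenesis and nucleolus genes (median -0.18, adjusted p = 0.0148, and an adjusted p of 0.842 with an estimated correlation) and blood cell markers (median 0.14, adjusted p = 0.0192, and an adjusted p of 0.711 with an estimated correlation) passed with 0 members called, and each lost its call with the array contrast as covariate (-0.11 and 0.13), without Nutlin-3 replicate 1 (-0.07 and 0.11) and without 5FU replicate 2 (-0.10 and 0.12). Without Nutlin-3 replicate 2 the interferon (-0.17) and stress response (0.005) lists lost their calls, and without 5FU replicate 1 the stress response list did (-0.02). With the 8920 genes of higher mean alone, the NF-kappaB (-0.20), interferon (0.001), ribosome biogenesis (-0.18) and blood cell (0.08) lists lost theirs. The interferon list also lost its call with upper-quartile probe sets (-0.16), the blood cell list with the median over probe sets (0.14) and the stress response list with all probe sets (0.04). Fry called the NF-kappaB and interferon lists, and not the immediate early (adjusted p = 0.105), blood cell (0.377), stress response (0.705) or ribosome biogenesis (0.705) lists.

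The p53 target lists did not pass between the drugs. Their medians of Nutlin-3 minus 5FU were -0.14 for cell-cycle arrest and growth (camera adjusted p = 0.172), -0.24 for apoptosis (adjusted p = 0.0962), 0.04 with a mean of -0.008 for negative feedback (adjusted p = 0.763) and 0.03 for DNA repair and metabolism (adjusted p = 0.214). MDM2 differed by 0.29 (95% interval -0.13 to 0.72, limma adjusted p = 0.55) and CDKN1A by 0.32 (0.02 to 0.61, unadjusted interval, adjusted p = 0.351). Replication-dependent histones had a median difference of -0.08 (adjusted p = 0.226). The RNA exosome (-0.28, adjusted p = 0.0686), cytosolic ribosomal proteins (-0.08, adjusted p = 0.34), cholesterol and fatty-acid synthesis (-0.10, adjusted p = 0.34), autophagy and lysosome genes (-0.06, adjusted p = 0.763), colonic epithelial genes (-0.005 with the camera direction up, adjusted p = 0.8) and fibroblast markers (0.04, adjusted p = 0.248) did not pass either. Exosome genes passed without control replicate 1 or control replicate 2 (-0.28 in both fits), Nutlin-3 replicate 2 (-0.51) or 5FU replicate 1 (-0.41), and with the crossed pairing or only the 2 groups compared (-0.28), and p53 targets in DNA repair and metabolism passed without Nutlin-3 replicate 1 (0.12). TYMS differed by -0.34 (-0.71 to 0.04, adjusted p = 0.429), ATM by -0.18 (-0.76 to 0.39, adjusted p = 0.787) and MET by 0.003 (-0.55 to 0.56, adjusted p = 0.996).

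**Figure D3:**
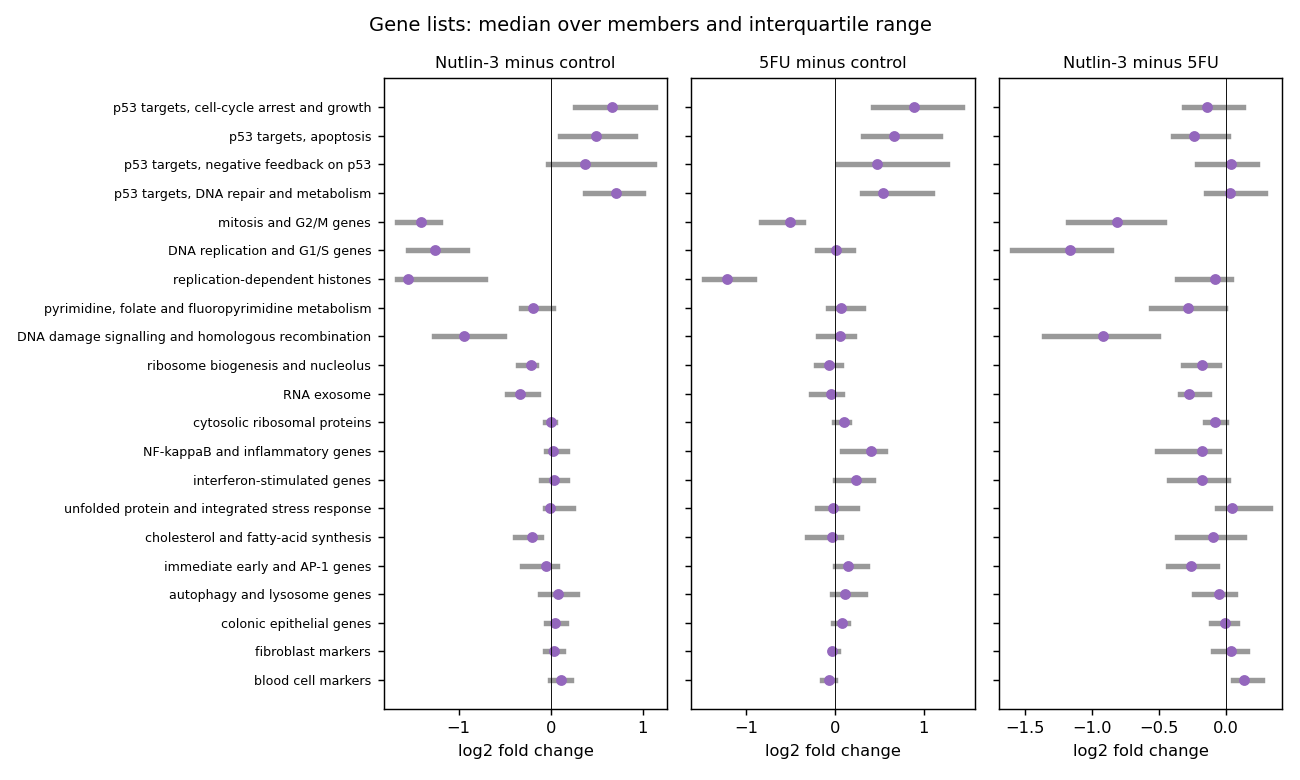
Median log2 fold change of the members of each of 21 gene lists (points) with the interquartile range over members (bars), for Nutlin-3 minus control, 5FU minus control and Nutlin-3 minus 5FU, each panel with its own horizontal scale. DNA replication and G1/S genes have medians of -1.26, 0.02 and -1.17 in the 3 panels, and mitosis and G2/M genes -1.41, -0.50 and -0.81.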

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

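Of the tests in this part, the fits with the array contrast and without control replicate 2 and Nutlin-3 replicate 1 were alternatives chosen after the data were seen. Results are given here where both Nutlin-3 arrays lay on one side of both controls and both 5FU arrays on the other, and the difference between the drugs passed limma's threshold (Benjamini-Hochberg), or where a gene list had medians of opposite sign against control, passed camera against control for 1 of the drugs and passed it between them. The first condition held for 47 genes, of which those named by the fixed rule are given. Among named genes, the log2 difference of Nutlin-3 minus 5FU was -4.53 in CCNE2, -3.11 in FAM111B, -2.94 in DTL, -2.54 in MYBL1, -2.54 in E2F8, -2.51 in TCF19, -2.42 in CDC25A, -1.25 in JUN, -1.19 in RRM2 and -1.16 in CCN1, with Nutlin-3 below and 5FU above control. It was 1.60 in NTSR1, 1.00 in PLPP6, 0.96 in NEK6, 0.93 in SLC39A11 and 0.90 in PLEKHH1, with Nutlin-3 above and 5FU below control. Of these genes, limma called the fall against control after Nutlin-3 in CCNE2, FAM111B, DTL, E2F8, TCF19 and CDC25A, called the fall after 5FU in NTSR1, and called no rise against control. The lists were DNA replication and G1/S genes with a median difference of -1.17, DNA damage signalling and homologous recombination with -0.92, pyrimidine, folate and fluoropyrimidine metabolism with -0.28 and immediate early and AP-1 genes with -0.26. In this order the adjusted p was 0.355, 0.527, 0.645 and 0.527 with an estimated correlation. The opposite sign rests on control replicate 2 for the replication and DNA damage lists: without it their medians for 5FU against control were both -0.14 and passed camera, and with all arrays the replication median was 0.015 with a camera direction of down. Immediate early genes lost their call for 5FU against control without control replicate 2 and Nutlin-3 replicate 1 together (median 0.07).

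The lower level of DNA replication and G1/S genes after Nutlin-3 than after 5FU was weighed against 3 technical explanations. With the contrast of each array as a covariate the list's median difference was -1.05, which argues against array contrast as the whole cause. With dim probe sets kept it was -1.11, and over fits that each left out 1 array the median nearest to 0 was -0.995, which argue against the filter and against 1 array. The comparison of the drugs on this list was fixed in advance. A different response to the drugs stays a hypothesis for the cause, since no batch is given in the sources used here and none was tested.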

How the results depend on the processing

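The fits with a crossed replicate pairing, with the array contrast as covariate and without control replicate 2 and Nutlin-3 replicate 1 were chosen after the data were seen. Counts below are in the order Nutlin-3 against control, 5FU against control and Nutlin-3 against 5FU, beside 217, 80 and 113 genes and 0, 0 and 10 probe sets, and beside 41 genes shared by the drugs. Replicate numbers did not pair the controls with the drugs, while the drugs went together by number: replicate differences correlated across genes at -0.565 between control and Nutlin-3, -0.525 between control and 5FU and 0.634 between the drugs. With the replicate block, limma called 2, 1 and 0 genes (1821 at an unadjusted p below 0.05 for the last), 1 shared gene and 0 probe sets for Nutlin-3 against 5FU (45089 unadjusted). With the crossed pairing, limma called 1788, 1882 and 2821 genes, 551 shared genes and 3 probe sets in the last comparison. With the array contrast as covariate the counts were 1577, 1989 and 2105, with 598 shared and 2 probe sets, and without control replicate 2 and Nutlin-3 replicate 1 they were 580, 592 and 650, with 208 shared and 48 probe sets. The axis behind these fits was found in the same residuals, which have 3 degrees of freedom, so the larger counts may be too high.

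With upper-quartile probe sets alone the counts were 380, 151 and 234 genes, 1531, 167 and 630 probe sets and 81 shared genes. With arrays centred on their medians they were 127, 14 and 37 genes, 9 shared and 0 probe sets for the last comparison (51634 unadjusted). The median over probe sets gave 39 and 69 genes in the last 2 comparisons and 22 shared, all probe sets of a gene gave 69 in the last, and array weights gave 186 genes and 21 probe sets there. Among probe sets, trend and robust variances gave 2696, 829 and 1606, quantile normalization 22 in the first and 21 in the last comparison, and for the last comparison no filter gave 0 (87300 unadjusted) and fitting only the 2 groups 0 (54306 unadjusted). Leaving out an array of the group not compared did not change the estimates. It gave the same gene counts as fitting only the 2 groups, 149, 63 and 104. Leaving out an array of a compared group, where a lone array was assumed to vary like the other groups, gave fewer genes than with all arrays. These counts are given with each comparison above, and for 5FU against control they were far below 80. Fewer arrays leave fewer degrees of freedom; the cause of the other changes was not tested.

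Of 36 list calls by camera, an estimated correlation left 0 (14 of 63 at an unadjusted p below 0.05) and fry called 16, of which 15 were shared, while each other setting called between 34 and 42. For 5FU against control, the median of ribosome biogenesis and nucleolus ran from -0.227 without control replicate 2 to 0.091 without control replicate 1, and that of DNA damage signalling from -0.14 without control replicate 2 (and without it and Nutlin-3 replicate 1) to 0.218 without control replicate 1; the cause was not tested. Of 114 calls of named genes 0 changed sign in the settings run, but 111 were lost with the replicate block, 62 with centred arrays, 85 without control replicate 1, 61 without control replicate 2, 55 without Nutlin-3 replicate 1, 38 without Nutlin-3 replicate 2, 64 without 5FU replicate 1 and 71 without 5FU replicate 2. The median over probe sets lost 38 of these calls, all probe sets of a gene 29 and only the 2 groups compared 21. With the crossed pairing or the array contrast 0 were lost. Detection above background was not measured in these values, and the filter on dim probe sets is only a weak stand-in for it. It passed 115 olfactory receptors and 14 blood cell markers, so passing it does not show that a gene was expressed. Changes with an end not far above the filter are therefore also less certain in size.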

Other observations

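The tests of probe sets without a symbol, of ACTA2 and of gene families, and the genes singled out here, were chosen after results were seen. Families were tested with camera over 10 families chosen by symbol. The 7 measured APOBEC3 cytidine deaminases had median log2 changes of 0.39 after Nutlin-3 (adjusted p = 0.00596) and 0.48 after 5FU (adjusted p = 7.48e-05), and APOBEC3C rose after each drug. Without APOBEC3C the median of the other 6 was 0.24 after Nutlin-3, which did not pass (adjusted p = 0.101), and 0.41 after 5FU (adjusted p = 0.00389). Proteasome subunits had a median of -0.18 after Nutlin-3 against control (adjusted p = 0.00136) and -0.27 against 5FU (adjusted p = 2.68e-05), with 0 of 47 called, and mitochondrial ribosomal proteins a median of -0.18 after Nutlin-3 (adjusted p = 0.000515), with 0 of 76 called. Clade B serpins, the family of SERPINB5, had a median of 0.30 after 5FU (adjusted p = 0.0259), with 6 of 9 above 0 and 1 called; without SERPINB5 the call was lost (median 0.27, adjusted p = 0.172). With an estimated correlation the adjusted p was 0.79 and 0.329 for APOBEC3, 0.929 and 0.667 for the proteasome, 0.929 for mitochondrial ribosomal proteins and 0.563 for serpins. Mitochondrial ribosomal proteins (-0.20, adjusted p = 0.0101), complex I subunits (-0.21, adjusted p = 0.0169), ZNF genes (-0.10, adjusted p = 0.0262) and olfactory receptors (0.08, adjusted p = 0.0236) also passed for Nutlin-3 against 5FU. With the array contrast as covariate these 4 calls were lost (adjusted p = 0.13, 0.111, 0.111 and 0.26), while the proteasome call between the drugs was not (adjusted p = 0.000433); the adjusted p of each was 0.667 with an estimated correlation. ZNF genes passed for 5FU against control (0.09, adjusted p = 0.0259), with an adjusted p of 0.915 with an estimated correlation. The calls of APOBEC3 genes, of proteasome subunits, of mitochondrial ribosomal proteins after Nutlin-3 against control and of serpins kept their direction and passed again after quantile normalization and with arrays centred on their medians. These settings could hardly change them, so this lends the calls little weight. The values were already normalized between arrays. Centring moves all genes of an array together, while camera compares a list with the other genes.

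NEAT1 and BCYRN1, which are non-coding RNAs, differed between Nutlin-3 and 5FU in limma (Benjamini-Hochberg adjusted p = 0.0383 and 0.0149). Non-coding RNAs were not tested as a group; 0 of 14 small nucleolar RNA host genes were called and that family did not pass camera (adjusted p = 0.166). NEAT1 lay at 10.07 and 10.47 on the Nutlin-3 arrays, 9.15 and 8.96 in control and 9.06 and 8.96 after 5FU. BCYRN1, a short neuronal RNA derived from an Alu element, lay at 11.33 and 11.41 after 5FU, 10.14 and 10.07 in control and 10.07 and 10.08 after Nutlin-3, with 4 probe sets; signal from related Alu copies was not separated. Single values near 16 appeared on 1 array each in probe sets annotated to RPL14 (5FU replicate 1, at most 13.29 on the other arrays) and FAM59A (5FU replicate 2, at most 13.74 elsewhere) and in 1 without a symbol (5FU replicate 2, at most 6.61 elsewhere).

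Replicate differences in the 3 groups shared 1 axis that held 73.9% of the within-group variance, with control replicate 1, Nutlin-3 replicate 2 and 5FU replicate 2 on one side. Along it, as 0.5 times the mean difference between replicates, the 1785 genes with the highest means had a median of 0.10 and the 1785 with the lowest means -0.05. The mitosis list had a median of 0.20, at percentile 100 of 10000 random lists matched on mean expression, whose central 95% ran from 0.03 to 0.12. The replication list was at percentile 99.2 and cytosolic ribosomal proteins at percentile 61.2. Random lists hold unrelated genes, so a list of genes that vary together leaves their range more easily. A difference in cycling state between cultures is therefore only a candidate explanation. In the 1038473 probe sets without a symbol, the same differences correlated between 0.084 and 0.087 across probe sets. These values lay between the bounds set for array contrast, so this test leaves that explanation undecided. The array contrast itself was 3.3636 in control replicate 1 and 3.2766 in control replicate 2. It was 3.3408 in Nutlin-3 replicate 2 and 3.2658 in replicate 1, and 3.3527 in 5FU replicate 2 and 3.3001 in replicate 1. In each group the array with the higher contrast lay on the same side of the axis, so array contrast is also a candidate explanation. Batches of cultures or arrays stay open because none is given in the sources used here.

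ACTA2 rose 3.21-fold after Nutlin-3 and 2.51-fold after 5FU. The other 14 fibroblast markers had medians of 0.029 after Nutlin-3 and -0.03 after 5FU against control, 0 passed limma's threshold, and the most abundant, COL6A1, at 7.90 in control, differed by 0.14 and -0.03, which argues against fibroblasts in the cultures. ACTA2 overlaps FAS in the RefSeq table. The difference ACTA2 minus FAS was 0.97 higher after Nutlin-3 than after 5FU (SE 0.21), which argues against FAS signal as the whole cause. Signal from other actin genes was not tested, and a change in ACTA2 itself stays a hypothesis.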
